A study of Mus musculus with 4 samples.

How the data were processed

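Immune cells sorted by FACS from digested mammary tumours were profiled with 10x Genomics 3' chemistry (kit v3.1 with 8000 cells loaded, per the labels' protocols). The labels list 4 samples, 2 PyMT and 2 Jagged1/PyMT, all at 12 weeks of age. The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 3.0.2, per the file headers and the submitters' processing notes. They were not normalised and not filtered for cells, since each lists 737280 barcodes, most of them empty. That number is the size of an older kit's barcode list, so the kit version given by the labels is not certain. The aligner, genome build and annotation release are not given in the sources used here. Both samples of a genotype are pooled in 1 matrix, and all barcodes carry the same suffix, so samples could not be told apart and each genotype was treated as 1 library. The matrices have 31053 features, and 30934 of their identifiers were found in GENCODE vM21 (GRCm38), which was used here for gene positions only.

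A barcode was called a cell with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs, which left 7444 PyMT and 7875 Jagged1/PyMT barcodes. Scrublet, as built into scanpy, scored doublets per library at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0.0403% and 0%, under the 0.5% limit below which it was taken to have failed, so the top expected share was removed (443 and 496 barcodes). Of all UMIs, 87.6% in PyMT and 85.2% in Jagged1/PyMT lay in the remaining cells, and 3.14% and 3.70% in barcodes under 100 UMIs, which were taken as free RNA.

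Cells of both libraries were clustered together without integration: counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen (without Jag1, mitochondrial, ribosomal, haemoglobin and immune receptor variable genes), and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 followed. Clusters were named from 21 fixed marker sets, and classes are called "-like" because no protein was measured. A cluster in which over 50% of barcodes held at least 3 UMIs of core genes of both T cells and macrophages was left out as mixed. Shares are percent of cells in named immune clusters. Levels are UMIs summed per library and class, divided by the class total and given as CPM. A gene with 0 UMIs in a library was set to a floor of 3 counts there, and such genes enter list medians at that value. It gives an approximate bound only, as the interval bound can lie nearer 0.

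Shares have exact binomial (Clopper-Pearson) 95% intervals and CPM exact Poisson intervals. Ratios of CPM have exact conditional binomial intervals. Ratios of shares, of T to B cells and of barcode counts have log-normal approximations, and list medians have intervals from 2000 Poisson draws. The 21 gene lists, computed in classes with at least 200 cells per library over members with at least 50 UMIs, covered alternative activation, T cell suppression by myeloid cells, lipid-associated and resident macrophages, inflammatory activation, MHC class I and II, interferon response, recruitment, Notch, glycolysis and hypoxia, cell cycle, dissociation stress, matrix remodelling, cytotoxic effectors, exhaustion, naive and memory, regulatory and activated T cells, and suppressive and immature neutrophils. Each median was placed among 10000 random lists drawn from the 50 genes on each side of every member in abundance. Shares of cells with a UMI were also taken in cells thinned to 1000 UMIs. Ratios in thinned cells are given without intervals. Thinning left 183 PyMT macrophage-like cells, so thinned ratios of genes with few UMIs are rough.

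Genes were named by a rule: the 10 higher and 10 lower genes of macrophage-like, monocyte-like and T cell-like cells (5 and 5 in B cell-like cells) with the largest log2 ratio, ranked by the interval bound nearest 0, among genes with at least 100 UMIs. Genes under their level in free RNA were left out, which removed 2833 genes in macrophage-like, 1041 in monocyte-like, 3606 in T cell-like and 1782 in B cell-like cells. Up to 4 members per list and a fixed set (Jag1, Notch1, Notch2, Il4i1, Cd274, Ccl2, Csf1, Csf1r, Cd8a, Cd4, Foxp3, Pdcd1, Ifng, Gzmb) could be named too. Other list members, and the neutrophil and NK cell genes, were chosen for naming after their values were seen.

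The ratio and list steps were tested on simulated Poisson counts drawn from the real class means, with no variation between cells or mice. The intervals assume the same model, so their coverage here checks the computation and not the spread of real data. For 9016 genes of macrophage-like cells, 95.9% of intervals of unchanged genes held the true value, and intervals excluded no difference for 71.6% of genes changed 1.5-fold and 97.0% changed 2-fold. For 8535 genes of T cell-like cells these were 95.6%, 91.0% and 98.5%. Lists of unchanged genes fell outside the central 95% of random lists in 5% of draws in each of these classes, and all 20 lists raised 1.5-fold lay above it.

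Cell filters, clustering, markers, lists, intervals and the naming rule were fixed before the data were examined. Alternatives tried were a minimum of 1000 UMIs, a minimum of 10% of the 99th percentile of the largest 8000 barcodes, mitochondrial limits of 5% and 20%, doublets kept, clustering at resolutions 0.5 and 2, libraries clustered apart, classes given per cell from markers, all called cells as the denominator, a list floor of 10 UMIs, thinned cells, means over cells, median-of-ratios scaling and subtraction of free RNA. The mixed cluster's rule, the runs without second lineage barcodes (at least 3 UMIs of another lineage's core genes) or with the mixed cluster counted in, and the neutrophil lists were added after seeing the data. One test of an explanation for the class shares, made from marker genes, is not reported here. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.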

Results

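Single-cell RNA was counted in immune cells that FACS had taken from mammary tumours of FVB/NJ mice aged 12 weeks. PyMT mice develop mammary tumours driven by the polyoma middle T antigen, and the genotype label Jagged1/PyMT also names Jagged1, a ligand of Notch receptors. The labels give 2 samples for each of the 2 genotypes, but both samples of a genotype share 1 matrix and no barcode is tied to a sample. Each genotype is therefore 1 library, so no test, p-value or spread between mice could be had, and the intervals given cover counting error only. The PyMT library held 36012036 UMIs and the Jagged1/PyMT library 55506773. After filtering, 7001 PyMT cells with a median of 3801 UMIs and 1270 genes remained, against 7379 Jagged1/PyMT cells with 4049 UMIs and 1324 genes.

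Jag1, the gene that the genotype names, was far higher in the Jagged1/PyMT library, with the largest ratios in epithelial-like and T cell-like cells. Over all called cells it had 64 UMIs in PyMT, or 2.03 CPM (95% exact Poisson interval 1.56 to 2.59), and 803 UMIs in Jagged1/PyMT, or 17.0 CPM (15.8 to 18.2), an 8.37-fold difference (6.48 to 10.97). In the few epithelial-like cells that the immune sort let through, it had 1.93 CPM in PyMT and 289 CPM in Jagged1/PyMT, and 2 of 103 against 27 of 48 cells held a Jag1 UMI. T cell-like cells had 4 Jag1 UMIs (0.202 CPM) in PyMT and 239 (22.6 CPM) in Jagged1/PyMT, a log2 ratio of 6.81 (5.43 to 8.69). NK cell-like cells (4.90 and 34.6 CPM) and dendritic cell-like cells (23.7 and 37.0 CPM) had a higher Jagged1/PyMT level than T cell-like cells. The dendritic log2 ratio was 0.64 (-0.23 to 1.54). In macrophage-like cells the level hardly differed, at 13.3 and 12.3 CPM, a log2 ratio of -0.11 (-0.72 to 0.57). Jag1 (ENSMUSG00000027276) lies on the minus strand of chromosome 2 from 137081456 to 137116644 in GRCm38 (GENCODE vM21, used here for its position only).

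The share of cells with a Jag1 UMI set T cell-like cells apart from B cell-like cells. At equal depth (1000 UMIs drawn per cell), 2.38% of T cell-like cells (1.82% to 3.06%) and 0.549% of B cell-like cells (0.221% to 1.13%) of the Jagged1/PyMT library had one, against 0.0213% and 0% in PyMT. Without thinning the shares were 7.86% of T cell-like cells at a median of 3723 UMIs and 1.23% of B cell-like cells at 3179.5 UMIs. NK cell-like cells reached 25.9% in Jagged1/PyMT and 3.25% in PyMT (4.31% and 0% at equal depth). Barcodes with UMIs of a second lineage were 26.7% of NK cell-like cells in Jagged1/PyMT and 4.07% in PyMT. Among T cell-like cells of the Jagged1/PyMT library, 10.5% of those with a Cd4 UMI and no Cd8 UMI held a Jag1 UMI (8.34% to 12.9%), as did 6.10% of those with a Cd8 UMI and no Cd4 UMI (4.48% to 8.07%). By cluster the share did not simply follow Cd4 and Cd8. It was 12.0% (7.79% to 17.5%) in cluster 6 and 4.14% (2.64% to 6.15%) in cluster 4, both with Cd8b1 among their leading genes. In cluster 8, with Ctla4 and Foxp3 among its leading genes, it was 2.87% (0.939% to 6.58%). Barcodes under 100 UMIs, which hold free RNA, had Jag1 at 6.19 CPM in PyMT and 15.1 CPM in Jagged1/PyMT.

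**Figure D1:**
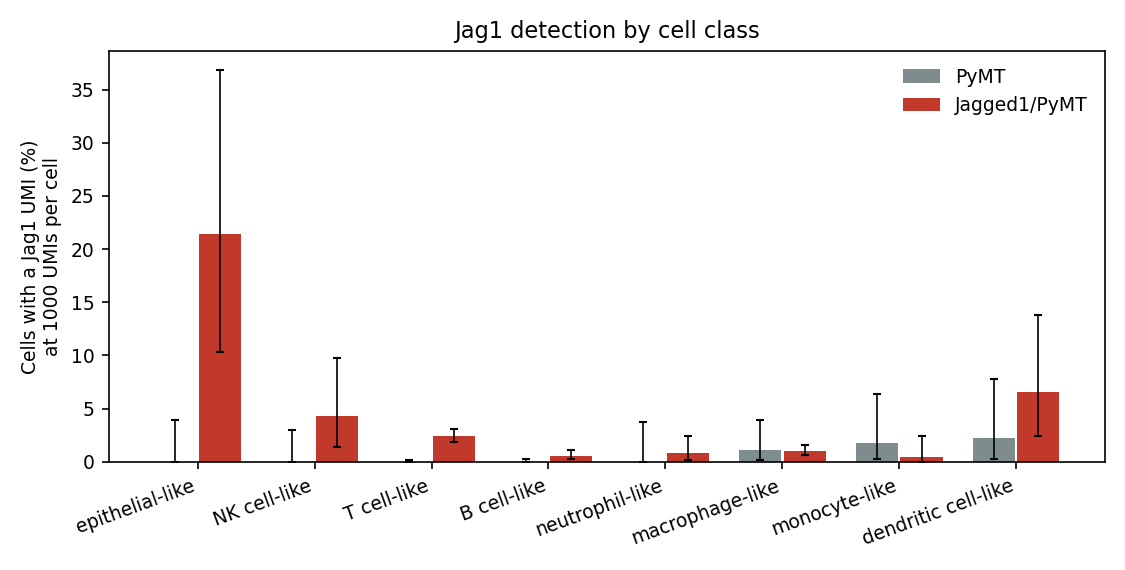
Percent of cells with at least 1 Jag1 UMI after thinning to 1000 UMIs per cell, for each cell class (x axis) of the PyMT (grey) and Jagged1/PyMT (red) libraries, with exact binomial 95% intervals from counting error. T cell-like cells stand at 2.38% in Jagged1/PyMT and 0.0213% in PyMT, while macrophage-like cells stand at 1.05% and 1.09%.

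The series title asks about macrophage recruitment, and macrophage-like cells were a far larger share of the sorted immune cells in Jagged1/PyMT. They made up 3.22% of 6773 immune cells in PyMT (218 cells, 95% exact binomial interval 2.81% to 3.67%) and 31.9% of 6906 in Jagged1/PyMT (2206 cells, 30.8% to 33.1%), a 9.92-fold higher share (8.67 to 11.4). The T cell-like share was lower by 1.87-fold, at 70.4% in PyMT (69.3% to 71.5%) and 37.6% in Jagged1/PyMT (36.4% to 38.7%). Neutrophil-like cells were 3.69-fold higher (2.96 to 4.60), at 1.45% and 5.34%, and monocyte-like cells 1.99-fold higher (1.59 to 2.49), at 1.64% and 3.26%. B cell-like cells (20.2% and 18.9%), NK cell-like cells (1.82% and 1.68%) and dendritic cell-like cells (1.36% and 1.35%) had ratios whose intervals included 1. The dendritic class held only mature (68 and 61) and plasmacytoid cells (24 and 32). No cluster of conventional dendritic cells was named at this resolution, so their share is not given.

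Cells fell into clusters that were unevenly filled by the libraries. T cell-like clusters 0 and 1 were mostly PyMT cells (1326 against 266, and 1283 against 375), whereas cluster 2 was mostly Jagged1/PyMT cells (564 against 1034). Cluster 4, led by Cd8b1 and Cd8a, held 1024 and 555 cells, and cluster 6, led by Ly6c2, Ctla2a and Nkg7, held 240 and 191. Macrophage-like cells came from cluster 9 (105 and 1326 cells), the shallow cluster 7 (107 and 723 cells, median 2361.5 UMIs) and the cycling cluster 17 (6 and 157 cells). A cluster with genes of both T cells and macrophages was left out of the classes, by a rule set after seeing the data. It held 1.79% of called cells in PyMT and 5.76% in Jagged1/PyMT. Counting it in with each class gave log2 ratios of 2.85 for the macrophage-like share, instead of 3.31, and of -0.78 for the T cell-like share, instead of -0.91. A share of sorted cells says nothing of cell numbers per tumour. The composition of the FACS gate was not given in the sources used here, and an unequal gate or digestion between the 2 libraries would move every share.

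**Figure D2:**
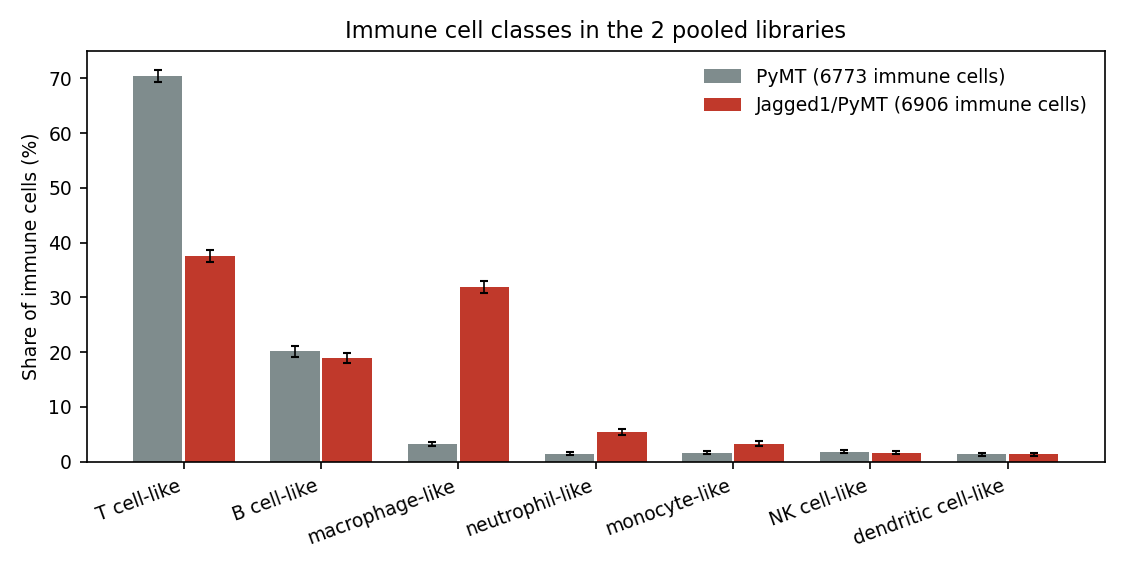
Percent of immune cells in each class (x axis) of the PyMT (grey, 6773 immune cells) and Jagged1/PyMT (red, 6906 immune cells) libraries after the FACS sort for immune cells, with exact binomial 95% intervals from counting error. Macrophage-like cells stand at 3.22% and 31.9%, and T cell-like cells at 70.4% and 37.6%.

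Within macrophage-like cells, glycolytic genes were higher in Jagged1/PyMT and genes of alternative activation mostly lower. Among 20 measured genes of the glycolysis and hypoxia list, 12 were over 1.5-fold higher and 0 over 1.5-fold lower, with a median log2 ratio of 0.69 (0.54 to 0.74). Phosphoglycerate kinase Pgk1 stood at 204 and 426 CPM (2.09-fold, 1.88 to 2.33), and triosephosphate isomerase Tpi1 at 309 and 629 CPM (2.04-fold, 1.87 to 2.23). The oxygen-sensitive genes Bnip3 and Ero1l both had log2 ratios of 0.98 (Ero1l 0.32 in cells thinned to 1000 UMIs), while Hif1a itself had -0.18 (-0.40 to 0.04). The cell cycle list was higher too, with 11 of 24 genes over 1.5-fold higher, 0 lower and a median of 0.50 (0.37 to 0.63). Its members Nusap1 (1.02) and Cdk1 (0.84) drive mitosis. The cycling cluster 17, at a median of 20505 UMIs, made up 6 of 218 PyMT and 157 of 2206 Jagged1/PyMT macrophage-like cells. As a description of these libraries, both medians lay at percentile 100 among 10000 random lists of matched abundance. The shallow cluster 7 made up 107 of 218 PyMT and 723 of 2206 Jagged1/PyMT macrophage-like cells. Ratios of the whole class, here and below, can therefore reflect its make-up.

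The alternative activation list, fixed for genes linked to tissue repair, had 7 of 13 measured genes over 1.5-fold lower and 2 over 1.5-fold higher. Its median log2 ratio was -0.87 (-0.97 to -0.23), at percentile 0 of the random lists, but -0.12 when cells were averaged instead of summed, -0.25 with the percentile rule for cells and -0.26 at the 5% mitochondrial limit. Il10, an anti-inflammatory cytokine, stood at 73.8 CPM in PyMT and 15.03 CPM in Jagged1/PyMT, a log2 ratio of -2.30 (-2.59 to -1.99), with UMIs in 34 and 132 cells. Its log2 ratio was -1.57 without barcodes of a second lineage and -0.66 in cells thinned to 1000 UMIs. The lectin Mgl2 (-1.38, and -2.15 without such barcodes) and the interleukin-1 receptor antagonist Il1rn (-0.995) were lower as well. Arg1, which depletes arginine, went the other way at 25.4 and 52.7 CPM (2.08-fold, 1.54 to 2.87), but only 8 PyMT cells held it. Its log2 ratio was 2.11 in thinned cells and 2.09 without barcodes of a second lineage, instead of 1.05. Without such barcodes Retnla was higher too, with 0 PyMT and 190 Jagged1/PyMT UMIs, at least 1.82 in log2.

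Genes by which myeloid cells restrain T cells did not move together in macrophage-like cells. Of 14 measured, 3 were over 1.5-fold higher and 2 over 1.5-fold lower, with a median log2 ratio of 0.04 (-0.04 to 0.24) at percentile 47.0. Cd274, which encodes PD-L1, stood at 9.80 and 17.0 CPM (a log2 ratio of 0.79, 0.09 to 1.58), but at 2.19 (0.63 to 4.48) without barcodes of a second lineage, where 3 of its PyMT UMIs were left, and the prostaglandin enzyme Ptgs2 had a log2 ratio of 0.66. At equal depth, 1.09% and 1.53% of macrophage-like cells held a Cd274 UMI, which is at or under the 1.85% and 4.40% of B cell-like cells, a class that expresses the gene too. Il4i1, an amino acid oxidase, had 4 and 54 UMIs, 2.31 CPM in each library, with a log2 ratio of 0.00 (-1.44 to 1.93). The poliovirus receptor Pvr was lower (-0.85, but -0.12 in thinned cells), as was Il10. Tgfb1 (0.04) and Lgals9 (0.02) hardly differed.

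Inflammatory and MHC class II genes were mostly lower in macrophage-like cells of Jagged1/PyMT. The inflammatory activation list had 6 of 17 genes over 1.5-fold lower and 2 higher, with a median log2 ratio of -0.26 at percentile 0.03. Il12b, a subunit of interleukin-12, had -1.70 (11 and 65 cells), the chemokine Cxcl1 -1.07, the adhesion molecule Icam1 -1.01 and Tnf -0.89, while Il1b had 0.05. The MHC class II list had a median of -0.24 (-0.32 to -0.19) at percentile 0.91, with H2-Eb1 at -0.66 and H2-Aa at -0.35, and 2 of 10 genes over 1.5-fold lower. MHC class I genes had a median of -0.19 (-0.28 to 0.02), which was 0.10 without barcodes of a second lineage, and the immunoproteasome genes Psmb8 (0.44) and Psmb9 (0.53) were higher.

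The recruitment list had a median log2 ratio of -0.13 at percentile 3.92 in macrophage-like cells, with 1 of 16 genes over 1.5-fold higher and 3 lower. Ccl7, a monocyte chemokine, was lower at 244 and 84.1 CPM (-1.54), but at -0.84 without barcodes of a second lineage and -0.96 in thinned cells. Ccl8 was higher (1.26), but at 0.76 (-0.10 to 1.77) without them. Ccl2 stood at 279 and 237 CPM (-0.23, -0.37 to -0.10), but at 0.17 in thinned cells. Csf1r, the receptor that maintains macrophages, stood at 735 and 684 CPM (-0.10, -0.19 to -0.02), and Csf1 had -0.39 (-0.82 to 0.07). The Notch pathway list had a median of -0.13 (-0.32 to 0.04) at percentile 11.9. Notch1 had -0.51 (-0.996 to 0.01) and Notch2 0.17 (-0.39 to 0.79). Without barcodes of a second lineage Notch2 had -0.29 (-0.998 to 0.51), from 17 PyMT UMIs. The Notch2 ratio of 2.01 in thinned cells has no interval and comes from only 183 PyMT cells, so it is too rough to show a difference.

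Further lists placed macrophage-like cells as follows. The interferon response list had a median log2 ratio of 0.29 (0.05 to 0.40) at percentile 99.7, with Xaf1 (0.87) and Cxcl10 (0.86) higher and Mx1 (-1.35) lower. Its median was -0.30 when the libraries were clustered apart, and Mx1 had 1.37 without barcodes of a second lineage. The dissociation stress list had 0.24 (0.16 to 0.30) at percentile 98.5, with Jun (0.85), Dusp1 (0.82) and Atf3 (0.82) higher. Lipid-associated genes had -0.11 at percentile 2.96, with Apoe at -0.31 and Ctsl at -1.17, which was 0.40 without barcodes of a second lineage. Resident macrophage genes had -0.01 at percentile 38.2, although Igf1 was higher (2.08, but 1.21 with an interval of -0.37 to 3.51 without such barcodes). Matrix genes had 0.04 at percentile 45.3, with Mmp13 at -1.72. Lists made for other cells had 0.11 (suppressive neutrophil), -0.05 (immature neutrophil), 0.04 (cytotoxic), -0.49 (exhaustion), -0.46 (naive and memory T cell), -0.75 (T cell activation) and -1.24 (regulatory T cell). Barcodes with UMIs of a second lineage were 26.1% of macrophage-like cells in PyMT and 22.03% in Jagged1/PyMT. Without them the last 3 of these medians were 0.43, 0.19 and 0.01. Those of the suppressive neutrophil, immature neutrophil, cytotoxic and exhaustion lists were then -0.03, -0.58, -0.18 and -0.39, and that of resident macrophage genes was 0.33.

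**Figure D3:**
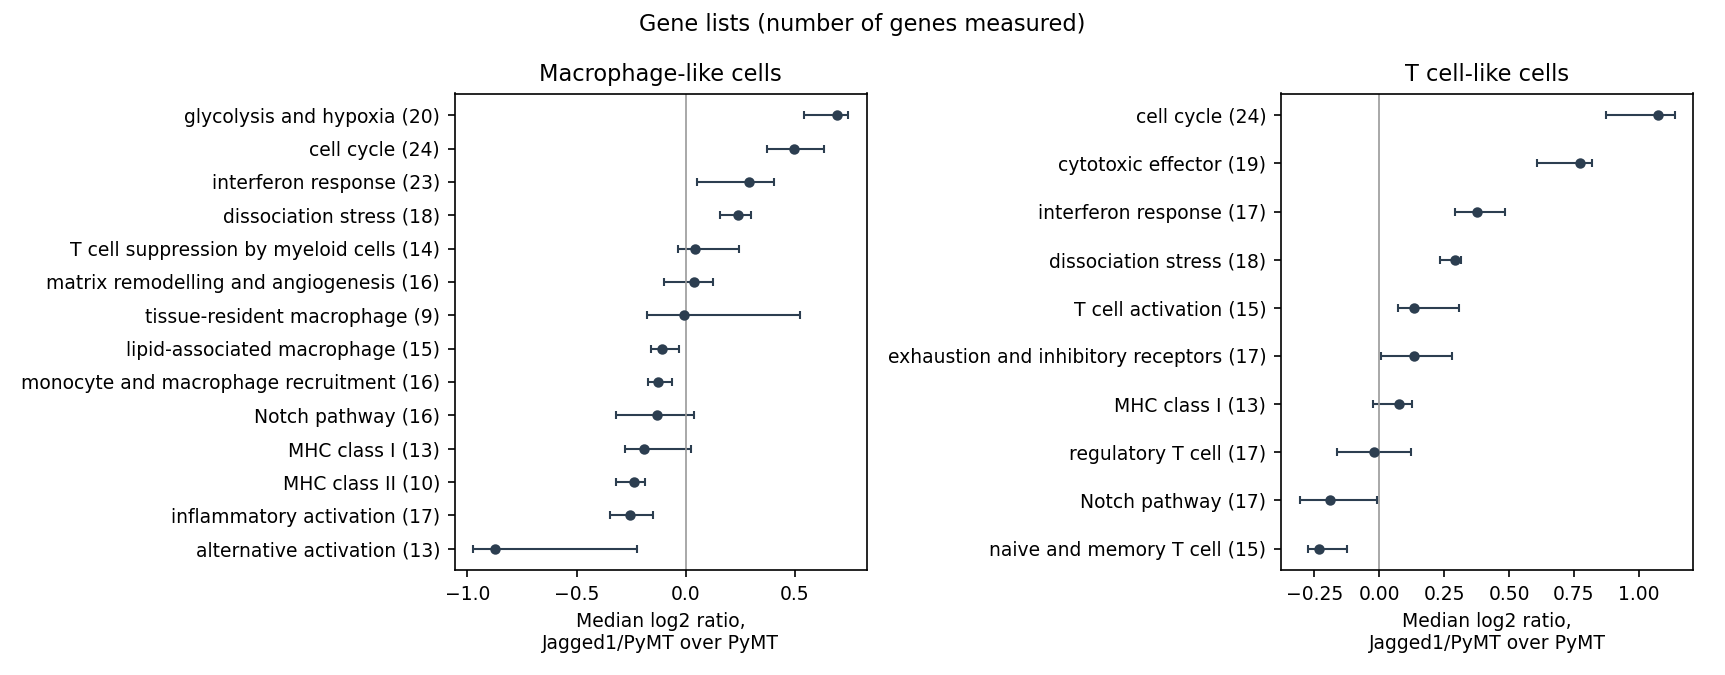
Median log2 ratio (Jagged1/PyMT over PyMT, x axes) of the measured genes of each list in macrophage-like cells (left) and T cell-like cells (right), with 95% intervals from Poisson draws of the counts and the number of measured genes in brackets. Glycolysis and hypoxia stands at 0.69 and alternative activation at -0.87 in macrophage-like cells, and cytotoxic effector at 0.77 in T cell-like cells.

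Of the 10 genes named by rule as higher in macrophage-like cells of Jagged1/PyMT, Pgk1 and Tpi1 rested on more than 100 PyMT cells. The other 8 had 5 or fewer PyMT UMIs. Chst14, a dermatan sulfotransferase, had 1 and 210 UMIs, a log2 ratio of 3.96 (1.47 to 9.27). Telo2 had 5 and 309 UMIs (2.20, but 0.73 in thinned cells). Inhba, a subunit of activin, had 0 and 139 UMIs, 3.44-fold higher at the floor of 3 PyMT counts, in only 18 cells. Fam71a (1.64 in log2 at that floor), Hist1h4k (3.63), Fabp4 (2.86), Gm38843 (2.42) and AA467197 (2.36) completed the list. Without barcodes of a second lineage Chst14 had 3.001, Hist1h4k 2.63, Fabp4 0.39 (-1.55 to 3.47) and Gm38843 1.48 (-0.10 to 3.77), and in thinned cells Fabp4 had 0.29. The 10 named as lower were Iqcb1 (-2.80), Il10, Gpnmb (-2.28), Egr3 (-2.26), Plk4 (-2.10), Mid1 (-2.09), Tnfrsf4 (-1.86), Mfge8 (-1.81), Il12b and Ccl7. Egr3, an early growth response factor, and Mid1 were spread over 35 and 36 PyMT cells. All PyMT UMIs of Gpnmb came from 4 cells. Without second lineage barcodes the differences of Gpnmb (0.10, -0.53 to 0.81), Plk4 (0.48, -0.93 to 2.38) and Mfge8 (0.63, -0.13 to 1.52) were lost, as these intervals hold 0. In that run Iqcb1 had -0.08 (-1.71 to 2.24), and Tnfrsf4 kept 0 of its 73 PyMT UMIs. In thinned cells Gpnmb had -0.48, Mfge8 -0.90, Tnfrsf4 -1.01, Plk4 0.57 and Mid1 -2.78.

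Monocyte-like cells, 111 in PyMT and 225 in Jagged1/PyMT, had more RNA of Saa3, Selenop, Pf4, Cbr2 and Folr2 in Jagged1/PyMT. The serum amyloid gene Saa3 stood at 8.93 and 150 CPM, a log2 ratio of 4.07 (3.25 to 5.03), in 7 and 31 cells. Selenop, which carries selenium, had 1.61 (1.46 to 1.75), the platelet factor Pf4 1.78 and Cbr2 1.77. The folate receptor Folr2, which is also on the resident macrophage list, had 1.73. Ccl12 (2.39), Cd209f (2.94), Fcna (2.05), Tmem37 (1.956) and Arg1 (2.08, from 1 and 4 cells) were also higher. Fscn1, an actin bundler of mature dendritic cells, was lower (-2.97, 6 and 10 cells), as were Hook2 (-2.01), Tbc1d4 (-1.74), Mt2 (-1.58), Slc20a1 (-1.54), Mdm2 (-1.44), Nr4a2 (-1.39), Tnip3 (-1.36), Slc38a2 (-1.28) and Adam8 (-1.17). Ccl2 stood at 568 and 773 CPM (0.45, 0.33 to 0.57). Second lineage barcodes were 34.2% and 38.2% of these cells. Without them Cd209f had 0 UMIs in both libraries, Fcna 0 and 7 and Arg1 0 and 10, Tbc1d4 had a log2 ratio of -0.68 (-1.42 to 0.07), Mt2 -3.07, Saa3 4.99, Ccl12 1.73, Pf4 3.12 and Cbr2 3.55. In thinned cells Pf4 had 0.85, Ccl12 1.48, Folr2 3.07, Tbc1d4 -0.37, Mdm2 -2.11, Adam8 -2.34 and Hook2 -3.13. At a clustering resolution of 2, a monocyte-like cluster with Cbr2, Pf4 and Mrc1 among its leading genes held 67 and 173 cells. A cDC2-like cluster held 44 and 56, so the libraries filled these 2 clusters unequally. Ratios of the whole class can therefore reflect its make-up. The PyMT library held fewer than the 200 cells that gene lists required.

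In neutrophil-like cells (98 and 369), the immature neutrophil list was higher in Jagged1/PyMT, with 10 of 12 genes over 1.5-fold higher and a median log2 ratio of 1.05 (0.88 to 1.27) at percentile 100. Granule genes led it, with the lactotransferrin gene Ltf at 4.66 and the cathelicidin gene Camp at 2.43, though Camp UMIs came from 2 and 26 cells. The suppressive neutrophil list had 7 of 18 genes over 1.5-fold lower and 2 higher, with a median of -0.41 (-0.51 to -0.26) at percentile 5.25. The arginase Arg2 had -1.18 and Cd14 -0.96, while Nos2 had 0 UMIs in PyMT and was at least 1.70 higher in log2. These lists were added for neutrophils after the data were seen, since the PyMT class is small.

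The series title also asks about suppressed T cells. T cell-like cells of Jagged1/PyMT had more RNA of cytotoxic and cell cycle genes. Of 19 measured cytotoxic effector genes, 11 were over 1.5-fold higher and 0 lower, with a median log2 ratio of 0.77 (0.61 to 0.82) at percentile 100. The granule protein gene Nkg7 stood at 120 and 206 CPM (0.77, 0.69 to 0.86), the chemokine Ccl5 at 0.78 and the transcription factor Eomes at 1.08. Gzmb, which encodes granzyme B, stood at 3.88 and 51.6 CPM (13.3-fold, 10.5 to 17.1), but in 22 and 36 cells, with 80.4% of the Jagged1/PyMT UMIs in 5 cells, and its log2 ratio of 3.73 was 2.22 in thinned cells. Perforin Prf1 (0.21, -0.02 to 0.44) and Ifng (0.16, -0.62 to 0.90) hardly differed. The cluster led by Ly6c2, Ctla2a and Nkg7 was also a larger part of T cell-like cells in Jagged1/PyMT (191 of 2595 cells, against 240 of 4766). The median of the list was 0.30 when the libraries were clustered apart and 0.43 at a clustering resolution of 0.5.

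The cell cycle list had 15 of 24 genes over 1.5-fold higher and 0 lower in T cell-like cells, with a median log2 ratio of 1.08 (0.87 to 1.14) at percentile 100. Mki67, a proliferation marker, stood at 12.7 and 36.7 CPM (1.53) from 33 and 45 cells. T cell activation genes had a median of 0.14 at percentile 95.4, with 4 of 15 over 1.5-fold higher and 0 lower. Among them the early activation marker Cd69 stood at 143 and 258 CPM (0.85), the CD40 ligand gene Cd40lg at 29.4 and 61.5 CPM (1.06, 0.90 to 1.23), and Irf4 had 1.55 (1.21 to 1.89). The interferon response list had 0.38 at percentile 99.95, with Xaf1 at 1.49, and the dissociation stress list had 0.29 at percentile 99.99.

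Exhaustion and inhibitory receptor genes were mixed in T cell-like cells. Of 17 measured, 4 were over 1.5-fold higher and 2 lower, and the median log2 ratio was 0.14 (0.01 to 0.28) at percentile 88.7, with values near 0 on the negative side under some clusterings. Pdcd1, which encodes PD-1, stood at 12.95 and 20.6 CPM (0.67, 0.40 to 0.93), and at equal depth 0.746% and 1.59% of T cell-like cells held a UMI, against 0% of B cell-like cells. Unthinned shares for Pdcd1 were 2.37% at a median of 3838 UMIs and 3.39% at 3723 UMIs. Bhlhe40 (0.87), Cd160 (1.12, 0.48 in thinned cells) and Entpd1 (1.14) were higher, whereas Nr4a3 (-1.10) and Nr4a2 (-0.62), which follow receptor signals, were lower. Ctla4 had 0.30, Tox 0.00 and Lag3 0.21 (-0.55 to 0.95).

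Naive and memory genes were slightly lower, with a median log2 ratio of -0.23 (-0.27 to -0.12) at percentile 0.28 in T cell-like cells. Satb1 (-0.58), Il7r (-0.48) and Lef1 (-0.38) were lower, and Igfbp4 (0.65) and Dapl1 (0.48) higher. The regulatory T cell list had -0.02 (-0.16 to 0.12) at percentile 36.3, with Tnfrsf18 at -0.67 and Areg at 1.62. Foxp3, which defines regulatory T cells, stood at 11.1 and 11.6 CPM (0.07, -0.26 to 0.39), but at 9.41 and 6.85 CPM (-0.46, -0.89 to -0.04) without barcodes of a second lineage. The ratio of cells with Cd8 and no Cd4 UMI to cells with Cd4 and no Cd8 UMI was 1.52 in PyMT and 1.99 in Jagged1/PyMT at equal depth, a log2 difference of 0.39 (0.11 to 0.66). Without thinning it was 0.857 and 1.003. Cd8a stood at 102 and 151 CPM (0.56) and Cd4 at 109 and 103 CPM (-0.08, -0.18 to 0.03).

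Genes of myeloid cells were also higher in T cell-like barcodes of Jagged1/PyMT. The recruitment list had a median log2 ratio of 1.9999, the suppressive neutrophil list 1.997, the lipid-associated list 0.95, the inflammatory list 0.85 and the MHC class II list 0.79. Barcodes with UMIs of a second lineage were 1.68% of T cell-like cells in PyMT and 6.17% in Jagged1/PyMT. Without them these medians were 1.41, 1.76, 0.54, 0.81 and 0.71, while the cytotoxic and cell cycle medians were 0.68 and 0.76. The Notch pathway list had -0.19 (-0.31 to -0.01) at percentile 4.32, Notch1 had 0.11 (-0.09 to 0.32) and Notch2 -0.12 (-0.41 to 0.16). MHC class I (0.08), T cell suppression (0.08), glycolysis (0.06) and matrix genes (0.30, from 5 genes) completed the lists with at least 3 measured genes.

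Among genes named by rule in T cell-like cells, the receptor activity modifying gene Ramp3 ranked top of those lower in Jagged1/PyMT, at 170 and 49.0 CPM, 3.46-fold lower, with UMIs in 1720 and 384 cells. The polyamine genes Amd1 (-1.52) and Amd2 (-1.33), Gcsh (-1.51), Tubb2a (-1.29), Spata7 (-1.28), Tcp11l2 (-1.20), Pou6f1 (-1.08), Rnf125 (-1.02) and Ctla2a (-0.95) were lower as well. Jag1, Il17a (6.64, in 3 and 15 cells), Gzmb, Hist1h1a (2.07), Irf4, Kif15 (1.46), Sh2d3c (1.43), Nusap1 (1.37), Top2a (1.09) and Cd40lg were the 10 higher. Ratios of single genes come from sums over cells, so a few cells with many UMIs can set them, and differences between mice of a genotype could not be seen.

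**Figure D4:**
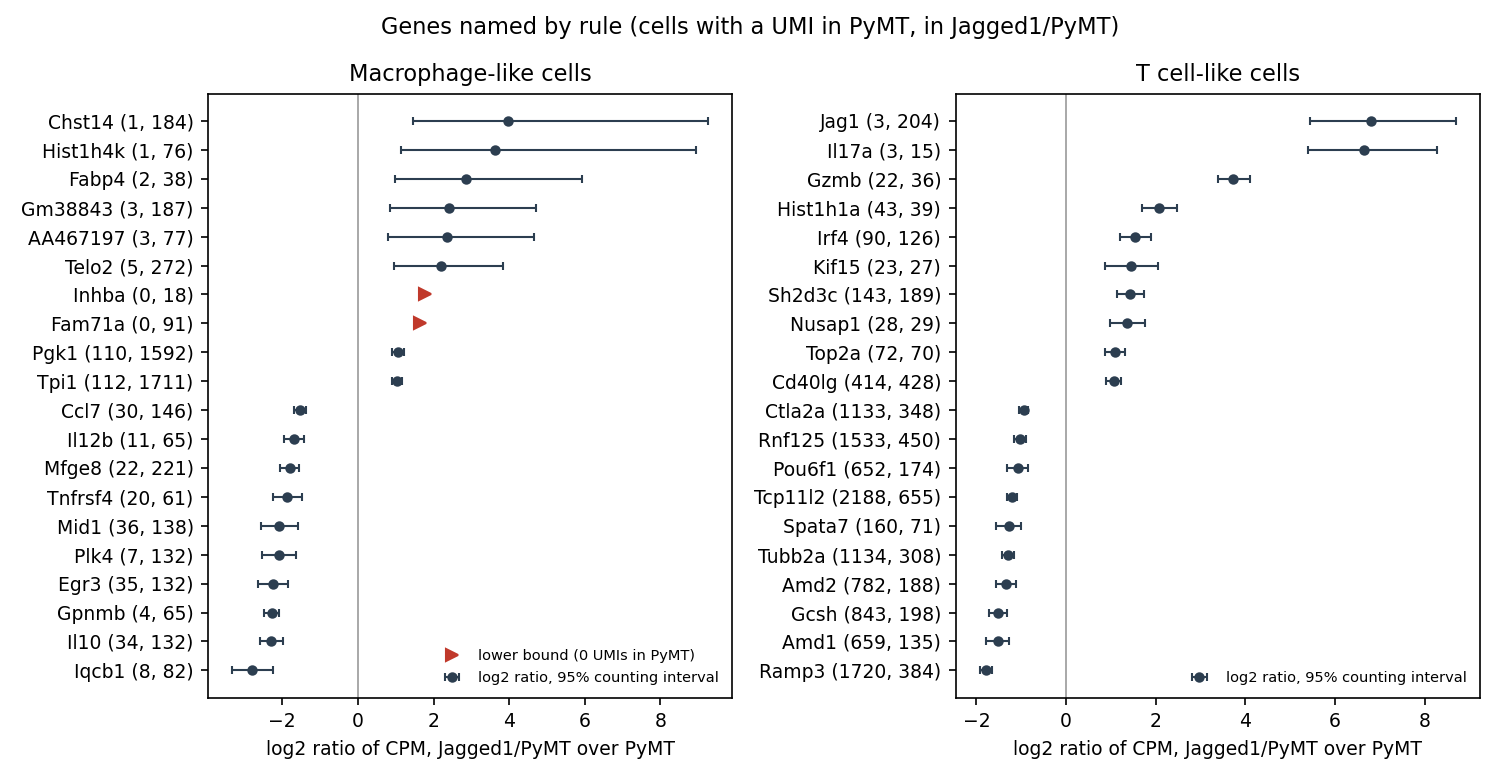
Log2 ratio of CPM (Jagged1/PyMT over PyMT, x axes) of the genes named by rule in macrophage-like cells (left) and T cell-like cells (right), with exact conditional 95% intervals from counting error; red triangles are lower bounds for genes with 0 PyMT UMIs, and brackets give cells with a UMI. In T cell-like cells Jag1 stands at 6.81 and Ramp3 at -1.79.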

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

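The tests below were all chosen only after the results were seen, as were the counting in of the mixed cluster and the run without second lineage barcodes, while the other processing alternatives cited were planned. Epithelial-like cells turned up in a sort for immune cells, at 1.47% of called cells in PyMT and 0.650% in Jagged1/PyMT, in data that the immune comparisons leave out. The cluster with genes of both T cells and macrophages, also outside the classes, held 1.79% of called cells in PyMT and 5.76% in Jagged1/PyMT.

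The first pattern is Jag1 RNA in T cell-like cells of the Jagged1/PyMT library, where 239 UMIs stood against 4 in PyMT. Free RNA alone is argued against, since 4.34 times as large a share of T cell-like as of B cell-like cells held a Jag1 UMI at equal depth (1.99 to 9.46), though both classes sat in the same free RNA. Tumour cells in the same droplets are argued against by 19 epithelial UMIs where the Jag1 UMIs would need 27186, which is 0.0699%, and macrophage RNA accounts for 0.783% of the Jag1 UMIs. Expression of Jag1 by T cells themselves in this genotype is a hypothesis that the tests leave open, and the same data gave rise to it. Whether the RNA came from an introduced copy or from the gene's own locus cannot be read from these 3' counts, and 1 library per genotype leaves differences between mice unseen.

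The second pattern is barcodes with at least 3 core UMIs of both T cells and macrophages, 298 in PyMT and 1307 in Jagged1/PyMT. Random doublets are argued against as the whole source, as these were 11.4 times (8.98 to 14.6) and 7.70 times (6.24 to 9.49) the number that T and B double barcodes predict. Free macrophage RNA is argued against as the whole source by 34.4% of T but 6.94% of B barcodes with macrophage core UMIs in Jagged1/PyMT. The fold between them was 4.96 (4.07 to 6.04). T barcodes here were any with at least 3 T cell core UMIs, and only 23.6% of the 1307 held more T cell than macrophage core UMIs. Free T cell RNA in macrophage barcodes was not tested, so it stays open. Macrophage fragments on or in T cells cannot be told apart from pairs of whole cells. In PyMT and Jagged1/PyMT these barcodes held a median of 17 and 56 macrophage core UMIs, which is 29.3% and 47.9% of the level of macrophage-like cells but 81.0% and 70.0% of that of barcodes with macrophage core UMIs alone, so the answer turns on the reference. Their T cell core UMIs (medians 13 and 12) were at the level of barcodes with T cell core UMIs alone (12 and 11). Their median total UMIs were 6365.5 and 10320, against 3900 and 3790.5 with T cell core UMIs alone and 4138 and 7289.5 with macrophage core UMIs alone. Deep barcodes reach 3 UMIs of both sets more easily, so these totals do not decide either. True contacts between the cells in the tumour stay open too.

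The third pattern is the higher macrophage-like and lower T cell-like share in Jagged1/PyMT. Dilution by added macrophages alone would leave the T to B ratio equal, but it was 3.49 in PyMT and 1.99 in Jagged1/PyMT, a log2 ratio of -0.81 (-0.94 to -0.68). Cell calls, doublet removal and class naming are argued against as the whole source, because the log2 ratio of the macrophage-like share ran from 2.85 to 4.28 over the alternatives. Lymph node or blood lymphocytes in the sorted cells stay open as well, with no test given here. The genotype stays among the open explanations, but genotype and library coincide here, so unequal dissection, digestion or sorting is as open.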

How the results depend on the processing

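No paired analysis was possible because the pooled matrices carry no sample numbers, and leaving out 1 sample at a time was not possible for the same reason. Of the log2 values that answer a comparison, 178 stayed within their counting interval, 34 moved, and 3 changed sign where that interval excluded 0. A further 18 of the stayed or moved values had the other sign, in 5 results whose interval held 0. All 10 alternative cell numbers stayed within 1.5-fold, the lowest being 5931 Jagged1/PyMT cells against 7379. The runs without second lineage barcodes, with the mixed cluster counted in, and the neutrophil lists were added after the data were seen. In what follows the cause was not tested. The log2 ratio of the macrophage-like share (3.31) was 3.54 with a minimum of 1000 UMIs, 3.93 with the percentile rule, 4.28 with libraries clustered apart (where a PyMT cluster of 295 cells led by Apoe and C1qa was left out as mixed), 3.01 with classes per cell, 3.53 without second lineage barcodes and 2.85 with the mixed cluster. The T cell-like share (-0.91) gave -0.97 with doublets kept, -0.83 with libraries apart, -0.81 per cell, -0.83 without second lineage barcodes and -0.78 with the mixed cluster. Monocyte-like cells (0.99) gave 1.39 with the percentile rule and 1.35 at resolution 2, neutrophil-like cells (1.88) 1.55 with the percentile rule, NK cell-like cells (-0.11) -0.80 per cell, and B cell-like cells (-0.10) -0.26 with the percentile rule and 0.033 without second lineage barcodes. In macrophage-like cells, alternative activation (-0.87) gave -0.12 as a mean over cells, and inside its wide interval -0.25 with the percentile rule and -0.26 at the 5% mitochondrial limit. T cell suppression (0.04) gave -0.19 in thinned cells. MHC class II gave -0.17 per cell, -0.34 thinned, -0.35 as a mean over cells and -0.39 without second lineage barcodes. Interferon response changed sign to -0.30 with libraries apart, where a cluster of interferon genes went unnamed, and gave 0.48 thinned, 0.50 as a mean over cells and 0.79 without second lineage barcodes. In T cell-like cells, cytotoxic genes gave 0.46 at 1000 UMIs, 0.43 at resolution 0.5, 0.30 with libraries apart and 0.57 as a mean over cells. Exhaustion changed sign to -0.0032 at resolution 0.5 and -0.00084 with libraries apart. Naive and memory genes gave -0.29 with the percentile rule, and regulatory T cell genes -0.50 with libraries apart (where the cluster with Foxp3 was named ILC2 in PyMT and left unnamed in Jagged1/PyMT), -0.25 per cell and 0.13 as a mean over cells. For single genes, 914 values stayed, 166 moved and 15 changed sign where the interval excluded 0, while 14 of the others, whose interval held 0, had the other sign, among them Foxp3 in T cell-like cells at -0.46 without second lineage barcodes. The 15 were, without second lineage barcodes, Gpnmb 0.10, Plk4 0.48, Mfge8 0.63, Ctsl 0.40, Mx1 1.37, Lef1 0.74 and Ccr7 0.95 in macrophage-like cells. In that run the intervals of Gpnmb, Plk4 and Mfge8 held 0, while that of Ctsl (0.19 to 0.62) did not. Those in thinned cells were Plk4 0.57, Maf -0.024, Dtx1 0.069, Pdgfa 2.16, Anxa1 0.19 and Ccl2 0.17 in macrophage-like, Wfdc17 -0.39 in B cell-like and Cd8a 1.30 in monocyte-like cells. These thinned values have no interval, with 183 PyMT macrophage-like and 111 PyMT monocyte-like cells of 1000 UMIs each. Counting error alone could therefore turn the sign of genes with few UMIs there. Estimated free RNA was at most 0.276% of a class, so its subtraction tested little. Depth limits small differences in the small classes, even in simulated Poisson counts with no variation between cells or mice. There, 65.7% of 1.5-fold differences were recovered in monocyte-like cells (111 in PyMT) and 71.6% in macrophage-like cells (218 in PyMT). In T cell-like cells 91.0% were recovered.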

Other observations

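B cell-like cells, 1365 in PyMT and 1302 in Jagged1/PyMT, had more RNA of Myc, Egr1 and Cd274 in Jagged1/PyMT. Myc stood at 311 and 662 CPM (2.13-fold, 1.999 to 2.27), Egr1 at 317 and 646 CPM (2.04-fold, 1.91 to 2.17), and Cd274 at 23.6 and 55.6 CPM (2.36-fold, 1.88 to 2.97), with UMIs of Cd274 in 100 and 175 cells. Gnb2 (0.91 in log2) and Rab30 (0.97) were the other genes named by rule as higher, and Usp2 (-1.74), Hepacam2 (-1.63), Rrp12 (-1.57), Slc38a2 (-1.11) and Id3 (-1.10) those as lower. The cluster led by Myc held 225 PyMT and 404 Jagged1/PyMT cells. The dissociation stress list had 9 of 17 genes over 1.5-fold higher and 0 lower, with a median log2 ratio of 0.59 at percentile 100, Jun at 1.64 and Hspa1a at 2.26, so genes that tissue handling can raise, Egr1 among them, were higher in the same library. The interferon response list had 0.55 at percentile 99.99, MHC class II -0.20 at percentile 0.65 and T cell activation genes 0.31 at percentile 99.7.

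Some small populations differed too, and Gzma, Prf1, Eomes and Apoe in NK cell-like cells were picked after their values were seen. Il17a, the cytokine of type 17 lymphocytes, had 5 UMIs in 3 PyMT T cell-like cells and 266 UMIs in 15 Jagged1/PyMT ones, and at resolution 2 a cluster led by Il17a and Cd163l1 held 12 and 21 cells. In NK cell-like cells (123 and 116), Gzma stood at 879 and 253 CPM, a log2 ratio of -1.80, Prf1 at 127 and 41.9 CPM (-1.60) and Eomes at 239 and 92.0 CPM (-1.38), while Gzmb stood at 1546 and 1927 CPM (0.32, 0.22 to 0.42). With the libraries clustered apart, PyMT had an NK cell-like cluster led by Gzma, Eomes and Ncr1 (51 cells) and one led by Gzmb and Gzmc (66 cells), and Jagged1/PyMT only one, led by Gzmb, Xcl1 and Gzmc (124 cells). The macrophage gene Apoe was higher in the same barcodes (4.47), where 4.07% in PyMT and 26.7% in Jagged1/PyMT held a second lineage. Dendritic cell-like cells were 68 and 61 mature cells and 24 and 32 plasmacytoid cells, and Il4i1 was high in the class in both libraries, at 475 and 384 CPM (-0.31, -0.53 to -0.09). No explanation was tested for these values.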
